A study of Mus musculus with 2 samples.

How the data were processed

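ChIP-seq for H3K36me3 was done on neural tube tissue of mouse embryos (strain B6NCrl) at embryonic day 12.5, with both sexes pooled. Per the labels, replicate 1 came from 120 embryos and replicate 2 from 88, so the replicates are separate pools of animals. The sources used here do not give the aligner, the peak caller or their versions.

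The authors deposited 4 peak lists in narrowPeak format on mm10. Per the deposited description files, each replicate's list was made from that replicate's filtered alignments with a control alignment, the pooled list from both replicates together, and the replicated list from both replicate lists and the pooled list. The rule by which a peak entered the replicated list is not given in the sources used here. The signal value of each peak was deposited by the authors as their caller gave it, relative to the control, and whether it is a fold enrichment is not stated. It was used to describe and rank peaks within a list, in the pairwise rank correlation of the replicates and in the comparison of chromosomes. The −log10 p and −log10 q of each peak were also taken as the authors deposited them. The lowest −log10 p was between 2.01 and 2.03 in every list, so the lists go down to weak peaks, and 83.1% of replicate 1 and 78.1% of replicate 2 peaks had a −log10 q of at least 2, against 98.5% in the replicated list. Deposited peak lists hold no read counts, so depth per replicate is unknown and coverage by peaks reflects both the mark and the power to call it. A gene without a peak is therefore a gene without a detected peak.

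Peaks were placed on the GENCODE M21 annotation of GRCm38 (the assembly also called mm10); all peaks ended within the chromosome lengths of that assembly on 21 of 21 chromosomes. Peaks on unplaced scaffolds (28, 10, 26 and 9 in the replicate 1, replicate 2, pooled and replicated lists) entered no comparison. Of 54 protein-coding entries that share a symbol with another, the longest per symbol was kept, so that 21911 of 21938 were used. The covered share of a gene is the percent of bases between its annotated start and end that lie in peaks, for each replicate's list, and its mean ± SD is over the 2 replicates. A gene was called marked at 10% or more in both. Intervals on shares are Wilson 95% intervals and cover counting error only.

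Overlap between lists required 1 bp. Chance levels came from 100 circular shifts of the peaks along the sequenced part of each chromosome, which keep widths and spacing; both replicate lists received the same shift when marked genes were counted. Shifts do not keep peaks away from sequence that cannot be mapped. Gene lists (29) were fixed before the data were examined and covered neural cell classes, other cell types, genes of general cell machinery and of dividing cells, and gene families. Older symbols were matched through RefSeq synonyms only where no annotated gene had that symbol. The median covered share of a list was compared with 10000 random lists of the same size matched on gene length in 20 quantile bins, two-sided, with Benjamini-Hochberg adjustment over the 29 lists. Tests against shifts and random lists are called permutation tests in the text. A median cannot fall below random lists whose median is near 0, so the number of marked members was compared with length-matched random lists in the same way; this test was added after the data were seen. Genes of a list are not independent samples, and these p-values describe the list against other genes of the same libraries, not variation between animals. Random lists could contain members of the tested list.

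Genes named in the text followed a rule written before the data were examined: in each list the 3 members with the highest and the 2 with the lowest mean covered share, the 10 genes of at least 10 kb with the highest share, the 5 of at least 10 kb with the largest replicate difference in each direction, the genes under the 10 longest domains, the genes nearest the 3 peaks with the highest signal, and Setd2. Not every gene so chosen is printed. Outside this rule, the 3 non-coding members of the imprinted list (Meg3, Kcnq1ot1 and H19), Cx3cr1, Eif4a1, Nono, Pgk1 and the genes of the last part were chosen after their values were seen.

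The alternatives were a −log10 q of at least 2, stricter overlap, equal numbers of peaks, the pooled list, genes of all types, random placement, each replicate alone, other minimums of coverage, length and gap, lists without length matching, the replicated list, genes without overlap and signal-weighted coverage. Functions were tested on simulated peaks over the 21911 genes: all of 2000 genes given 40% coverage were recovered as marked with 0 others, a 3' placement of 79% was measured as 79%, 20 of 20 enriched lists were found, and of 200 null lists 0 by the median and 1 by the count had an unadjusted p under 0.05. The simulated genes overlapped no other gene, and their peaks lay at the same places in both simulated lists. Far fewer genes were covered than in the data (7128 marked), and enriched lists were mostly covered genes. The simulation therefore checks the code, and does not show how the list tests behave on weaker differences in these data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.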

Results

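H3K36me3, a histone mark that the methyltransferase SETD2 places in transcribed gene bodies behind elongating RNA polymerase II, was mapped by ChIP-seq in mouse neural tube, the embryonic tissue that forms the brain and spinal cord, at embryonic day 12.5. There was 1 group with 2 biological replicates, each a pool of neural tubes from embryos of both sexes: 120 embryos in replicate 1 and 88 in replicate 2. The measurements are peak lists on mm10: 162655 peaks in replicate 1, 144869 in replicate 2, 157201 in a list called on both replicates pooled, and 110862 in the authors' replicated list. These lists covered 86.6 Mb, 84.1 Mb, 116 Mb and 103 Mb of the assembled chromosomes, in the same order. Peak lists give no read counts, so the read depth of the libraries is unknown here. With 1 tissue and 1 stage, the comparisons the design allows are between replicates, between kinds of sequence, between places in the gene body, between genes and between chromosomes.

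Most places marked in one replicate were also marked in the other. Of the replicate 1 peaks, 70.5% were overlapped by a replicate 2 peak (Wilson 95% interval 70.3% to 70.7%, 114660 of 162627 peaks on chromosomes), against a mean of 5.46% after circular shifts of the replicate 2 list. Of the replicate 2 peaks, 76.0% were overlapped by a replicate 1 peak (75.8% to 76.3%), against 5.97% after shifts. In each direction none of 100 shifts reached the observed share, giving a one-sided permutation p of 0.0099, the smallest that 100 shifts can give. Both lists shared 60.3 Mb, which was 69.7% of the replicate 1 bases and 71.7% of the replicate 2 bases. Peaks found in only 1 list were narrow and weak by the authors' signal value: in replicate 1 the median width was 244 bp without overlap and 434 bp with it, and the median signal was 2.65 and 3.19. Replicate 2 gave 241 bp and 441 bp, with median signals of 2.77 and 3.27. Across 114660 overlapping pairs, which are not independent replicates, the signal values had a Spearman correlation of 0.416. Requiring overlap of 50% of both peaks lowered the shared share to 38.6% of replicate 1 and 43.3% of replicate 2 peaks.

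The pooled list and the replicated list differed by small peaks. Each of the 110853 replicated peaks on chromosomes lay at the place of a pooled peak, and 46322 pooled peaks were left out. The kept peaks had a median width of 578 bp and a median signal of 3.07, and those left out 238 bp and 2.31, so that 70.5% of the pooled peaks were kept and 10.7% of the pooled bases were removed. Of the replicated peaks, 75.4% overlapped a peak in both replicate lists, 22.0% in 1 of them and 2.62% in neither, the last group holding 0.855% of the replicated bases.

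H3K36me3 lay in gene bodies. Of the replicated-list bases, 94.6% fell between the start and end of annotated protein-coding genes, against a mean of 41.5% for shifted peaks (2.28-fold). Introns held 69.6% of the bases (37.6% after shifts) and exons 25% (3.89% after shifts, 6.43-fold). Promoters, taken as 1 kb on each side of the annotated gene start, held 0.433%, against 1.66% after shifts (0.26-fold), and intergenic sequence held 5.38%, against 58.5%. All of these shares lay outside the range of 100 shifts (two-sided permutation p = 0.0198, the smallest they can give). The gene body share was 94.4% in replicate 1 and 94.8% in replicate 2. With genes of every annotated type the promoter share was 3.04%, against 3.92% after shifts.

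Within genes the mark rose from the start to near the end of transcription. In the 5396 marked protein-coding genes of at least 10 kb (marked genes are defined below by coverage in both replicates), the mean covered share in the replicated list was 5.67% in part 1 of 10 equal parts of the gene body, 22.2% in part 2, 46.3% in part 5 and 63.8% in part 9, with 60.7% in the last. Replicate 1 went from 4.78% in part 1 to 53.6% in part 9, and replicate 2 from 4.41% to 54.6%. More bases were covered on the 3' side than on the 5' side of the gene midpoint in 4726 of these 5396 genes, or 87.6%, where shifted lists gave 50.3% and at most 54.1% (two-sided permutation p = 0.0198, the smallest possible). Inside the same genes exons were covered more than introns: 59.5% of exonic and 40.6% of intronic bases on average, with exons higher in 80.9% of the genes. Position along the gene was not held fixed, so this difference cannot be separated from the rise toward the gene end. In the replicate lists alone, exon and intron shares were 50.6% and 33.5% in replicate 1 and 51.8% and 33.5% in replicate 2.

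**Figure D1:**
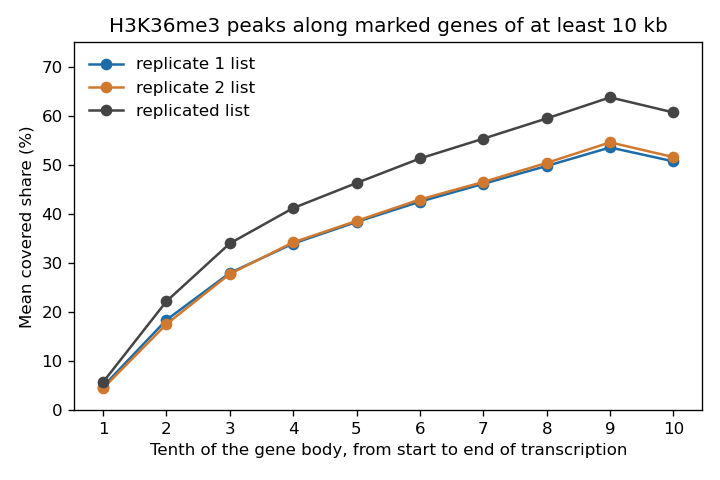
Mean covered share (%) of each of 10 equal parts of the gene body, from the start (1) to the end (10) of transcription, in 5396 marked protein-coding genes of at least 10 kb, for each replicate's list and the replicated list. Coverage was lowest in part 1 (5.67% in the replicated list) and highest in part 9 (63.8%), where replicates 1 and 2 stood at 53.6% and 54.6%.

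A gene was called marked when peaks covered at least 10% of its body in both replicates. Of 21911 protein-coding genes, 7128 were marked (32.5%), where shifted lists gave a mean of 1961 and at most 2170. No peak of either replicate touched 10198 genes (46.5%), and 1678 genes were covered over 50% or more of their length in both replicates. The mean covered share of a gene correlated across genes between the replicates (Spearman 0.956; genes are not independent replicates). Among marked genes the median difference between replicates was 2.67 percentage points. Marking was most frequent at intermediate length: 44.8% of genes between 12 and 25.2 kb were marked, against 16.0% of those up to 5.27 kb and 25% of those from 58.1 kb. With a minimum of 25% in place of 10%, 4623 genes were marked. Of the 7128 marked genes, 2195 (30.8%) overlapped another protein-coding gene, against 21.5% of all protein-coding genes. Peaks in the shared sequence cannot be assigned to a single gene. Genes named below with such overlap include Mybbp1a, Zfp335, Ssrp1, Supt6, Crmp1 and Tubb3.

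The gene with the highest covered share among those of at least 10 kb was Scrib, a cell polarity scaffold (ENSMUSG00000022568.17, chromosome 15), at 87.8% ± 0.16 (SD, n = 2). Mybbp1a, a nucleolar transcription regulator, followed at 87.5% ± 0.48 and Exosc10, a nuclease of the RNA exosome, at 87.3% ± 2.49. Prr12 stood at 87.1% ± 1.18, the ubiquitin ligase gene Rnf40 at 86.9% ± 1.36, Kdm4a at 86.9% ± 1.11, Zfp335 at 86.9% ± 0.24, Zfp606 at 86.4% ± 0.06, the fatty acid synthase gene Fasn at 86.4% ± 3.76 and the Integrator subunit gene Ints1 at 85.9% ± 1.56. Setd2 itself (chromosome 9, 110532597 to 110618633) was covered over 36.2% ± 2.49.

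Genes of general cell machinery, of dividing cells and of H3K36 methylation were marked most often. Of 41 spliceosome and RNA-binding genes, 40 were marked, with a median covered share of 59.3%; the core splicing factors Sf3a1, Snrnp200 and Prpf8 stood at 85.8% ± 3.72, 85.3% ± 1.52 and 84.1% ± 1.27 (SD, n = 2), while Srsf2 (10.6% ± 5.93) passed the minimum in replicate 1 only. DNA replication and mitosis genes were marked in 38 of 39 cases, with the condensin gene Ncapd2 at 85.7% ± 0.59 and the replicative helicase gene Mcm2 at 73.3% ± 8.40; the exception was the X-linked Pola1 at 0.26% ± 0.29. Proteasome genes were marked in 30 of 31 cases (Psmc4 85.5% ± 3.72, Psmc1 78.5% ± 0.13; Psmd14 2.80% ± 0.93 was the exception). RNA polymerase II and elongation genes were marked in 30 of 34 cases, among them the chromatin factors Ssrp1 (71.5% ± 3.29) and Supt6 (70.2% ± 0.17), with Ell2 and Polr2i at 0. Ribosomal protein genes were marked in 60 of 79 cases, led by Rps3 (75.9% ± 0.99) and Rps15a (74.2% ± 1.35), and general housekeeping genes in 20 of 28, led by the elongation factor gene Eef2 (82.0% ± 0.30) and Hsp90ab1 (75.8% ± 1.78). The lowest housekeeping members were Tuba1b at 0.11% ± 0.16 and the X-linked Hprt at 1.93% ± 0.66. Writers, erasers and readers of H3K36 methylation were marked in 22 of 29 cases, from Kdm4a and Glyr1 (78.5% ± 2.10) down to Kdm4d and Phf19 at 0. The 7 median covered shares ran from 31% for housekeeping genes to 59.3% for spliceosome genes, where length-matched random lists had medians between 0 and 3.87%. All of the 7 lists lay above their random lists (adjusted permutation p of 0.0058 for housekeeping genes and 0.000828 for each of the other 6, two-sided, Benjamini-Hochberg over 29 lists, 0.000828 being the smallest reached). Their counts of marked members also lay above length-matched random lists (adjusted permutation p of 0.000773 for housekeeping genes and for the H3K36 methylation genes, and 0.000446 for the other 5).

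Zfp genes, which encode zinc finger proteins, also stood above chance. Of 365 measured members 242 were marked, against 145 expected from length-matched lists (adjusted permutation p = 0.000446), and their median covered share was 23.4% against 2.53% (adjusted permutation p = 0.000828). Zfp869 (90.7% ± 8.10), Zfp335 and Zfp606 were highest, and Zfp114 and Zfp174 were at 0. The highest signal value in the replicated list belonged to a 3736 bp peak over Zfp146 (chromosome 7, 30160623 to 30164358), of which 53.7% was exonic. The next were a 13947 bp peak in Srebf2, the sterol-responsive transcription factor gene (chromosome 15, 82176378 to 82190324, 8.02% exonic, signal 13.4), and a 10430 bp peak in the splicing factor gene Srrm2 (chromosome 17, 23813829 to 23824258, 75.5% exonic, signal 12.8).

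Neural genes were mixed. Among 36 pan-neuronal genes 14 were marked, led by the axonal motor gene Kif1a at 53.4% ± 0.20, the collapsin response gene Crmp1 at 43.4% ± 5.80 and the neuronal tubulin gene Tubb3 at 39.0% ± 3.65 (SD, n = 2), while the axon guidance receptor gene Robo2 (0.02% ± 0.03) and Gap43 (0.13% ± 0.18) were nearly bare. Their median of 7.36% exceeded the 0.728% of length-matched lists (adjusted permutation p = 0.0084), but not that of lists without length matching (adjusted permutation p = 0.299). Their count of 14 against 8.48 expected had an adjusted permutation p of 0.0474, which rose to 0.0568 with replicate 2 alone, 0.0965 without overlapping genes, 0.243 with a −log10 q of at least 2 and 0.908 with a 25% minimum (5 marked); with a 5% minimum 22 were marked (0.00061). Of 25 neural progenitor genes 9 were marked, against 6.16 expected (adjusted permutation p = 0.284). Msi1, an RNA-binding protein gene of neural stem cells, stood at 67.1% ± 6.27, the proteoglycan gene Ncan at 65.6% ± 6.40 and the intermediate filament gene Vim at 48.2% ± 3.91, and Fabp7 and Hes1 at 0. The progenitor median of 3.77% did not differ from random lists (adjusted permutation p = 0.264), except over genes that overlap no other protein-coding gene (6.26%, adjusted permutation p = 0.0375).

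Genes that pattern the neural tube or mark its neuron classes were largely unmarked. Of 34 dorsoventral patterning genes only Ptch1, the Hedgehog receptor gene, was marked, at 43.7% ± 1.04, against 8.44 genes expected (adjusted permutation p = 0.00102, or 0.0517 with a 25% minimum); Gli2 (10% ± 0.41) and Zic1 (9.10% ± 1.72) came next, and Ascl1 and Atoh1 were at 0. The patterning count was 3 with replicate 1 alone, where Gli2 and Zic1 also passed (adjusted permutation p = 0.0121), 1 with replicate 2 alone and 4 with a 5% minimum (0.028). None of 38 spinal interneuron and motor neuron genes was marked, against 12.4 expected (adjusted permutation p = 0.000446); the glycine transporter gene Slc6a5 (4.19% ± 3.22) and Lhx1 (3.40% ± 0.95) were highest. None of 26 forebrain and midbrain regulators was marked (7.88 expected, adjusted permutation p = 0.000446), and Satb2 at 0.58% ± 0.45 was the only member any peak touched. Hox genes did not differ from chance, with 9 of 39 marked against 10.2 expected (adjusted permutation p = 0.812), with 2 marked at a 25% minimum and 4 among genes without overlap, led by Hoxa5 (48.0% ± 22.6), Hoxb5 (37.1% ± 0.86) and Hoxa6 (25.8% ± 1.54). Of 25 imprinted genes 10 were marked (8 expected, adjusted permutation p = 0.513), with Nnat at 55.6% ± 6.36, Igf2r at 44.5% ± 3.93 and Rtl1 at 31.7% ± 0.20. Of the non-coding members of that list, Meg3 was covered over 27.9% and 36.7% in replicates 1 and 2, Kcnq1ot1 over 4.95% and 4.40%, and H19 over 8.41% and 0. Nnat overlaps another protein-coding gene, so its coverage cannot be assigned to Nnat alone, and overlap with non-coding genes was not considered.

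Lists for other cell types that a dissection could hold, and for several gene families, were mostly bare. Transcription was not measured, so an unmarked gene is not shown to be silent. None of 30 hepatocyte genes, 27 germline and pluripotency genes, 22 keratin and epidermal genes, 1134 olfactory receptor genes or 328 vomeronasal receptor genes was marked (adjusted permutation p = 0.000446 for each), nor any of 22 skeletal muscle genes (adjusted permutation p = 0.00102) or 21 neural crest and sensory ganglion genes (adjusted permutation p = 0.00129). Endothelial genes had 1 of 22 marked (Mmrn2, 11.1% ± 1.01; adjusted permutation p = 0.00244), mesenchyme and meninges genes 2 of 25 (the matrix genes Fn1, 42.7% ± 1.62, and Fbln1, 21.7% ± 1.54; adjusted permutation p = 0.00377) and cartilage genes 1 of 15 (the collagen gene Col2a1, 55.5% ± 4.03; adjusted permutation p = 0.018). Erythroid genes had 2 of 21 (the transferrin receptor gene Tfrc, 45.6% ± 2.35, which is also on the housekeeping list, and Nfe2, 11.5% ± 0.37; adjusted permutation p = 0.0826). Microglia and immune genes had 4 of 20, against 5.94 expected (adjusted permutation p = 0.513): Cd68 at 97.6% ± 3.35, Fcer1g at 17.0% ± 4.00, Coro1a at 13.3% ± 0.71 and Cx3cr1. Each of these 4 overlapped another marked gene or lay within 1 kb of it, Cd68 being 1.94 kb long and 0.782 kb from Eif4a1. None of 66 canonical histone genes was marked, but 4.20 were expected at their length (adjusted permutation p = 0.0214). Among clustered protocadherin genes the marked members were the 21 of 21 in the gamma cluster (median covered share 32.6%), which overlap one another and so are not separate observations, and none of 13 alpha genes (1.78%) or 22 beta genes (0) was marked. Over the 3 clusters 21 of 56 were marked (13 expected, adjusted permutation p = 0.0214, or 0.301 with a 5% minimum). Without genes that overlap others, the adjusted permutation p was 0.0605 for endothelial, 0.0907 for cartilage and 0.288 for histone genes. With a 25% minimum it was 0.164 for cartilage and 0.0867 for histone genes, and with a 5% minimum 0.0338 for erythroid genes. At 25% the imprinted count was 4, the erythroid, microglia and mesenchyme counts 1 each and the endothelial count 0, and without overlapping genes the microglia count was 2. The median covered share did not separate any list of this paragraph or the one before it from its random lists, since those medians were often near 0 themselves.

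**Figure D2:**
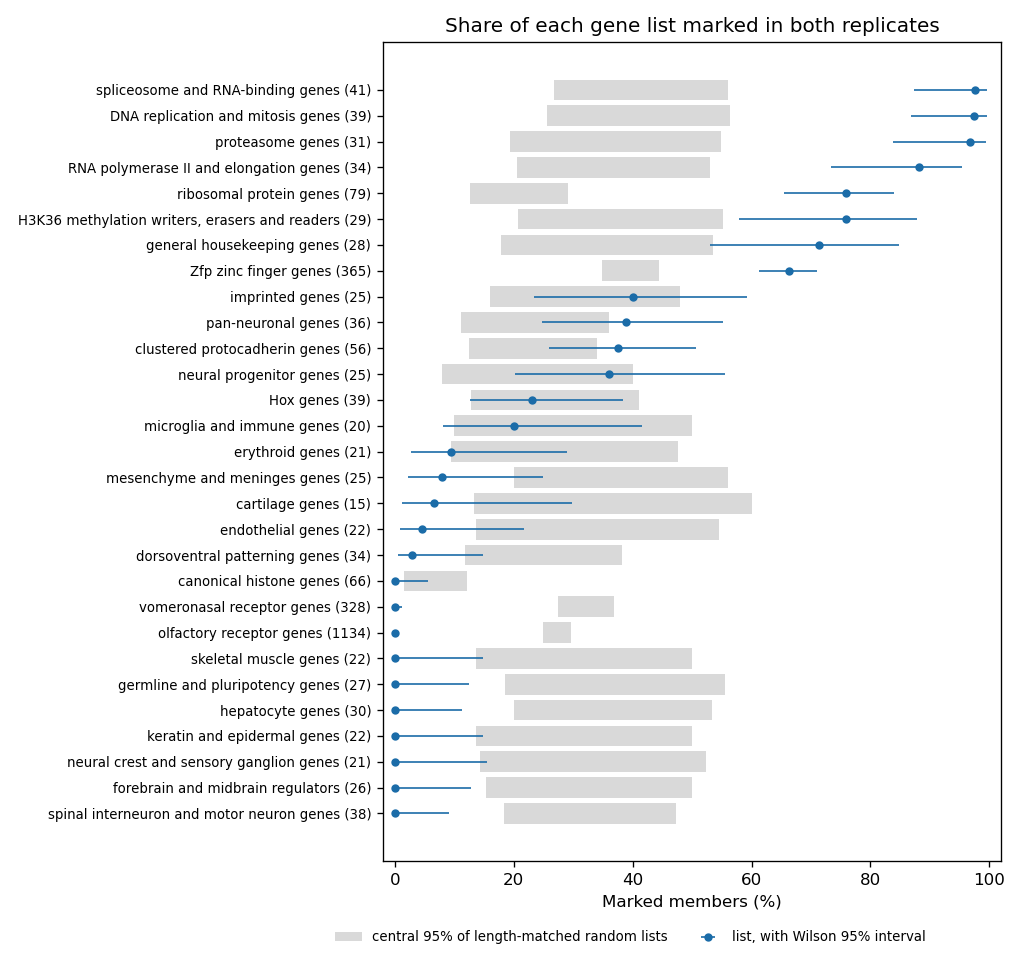
Share of each gene list (%) marked in both replicates, as points with Wilson 95% intervals, with the number of measured genes in brackets; grey bars span the central 95% of 10000 length-matched random lists. Spliceosome genes (40 of 41), DNA replication genes (38 of 39) and proteasome genes (30 of 31) lay to the right of their grey bars, and spinal interneuron and motor neuron genes (0 of 38) to the left.

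Part of the marked sequence formed broad domains. Joining replicated peaks over gaps of up to 3 kb gave 21550 domains with a median length of 2823 bp, of which 2222 reached 20 kb and 255 reached 50 kb; these figures depend on the gap, with 38899 domains at 1 kb and 11451 at 10 kb. At 3 kb, 7556 domains (35.1%) were a single peak, and domains of 20 kb or more held 42.2% of the replicated peaks. The longest domain was 132 kb on chromosome 4 (148452118 to 148583950), 86.2% covered, over the kinase gene Mtor, Angptl7, which lies inside Mtor, and Exosc10. Domains of 131 kb, 130 kb and 124 kb followed on chromosome 5, over the autophagy gene Wdfy3, over Hectd4 and Trafd1, and over Depdc5. The remaining 6 of the 10 longest lay over Mdn1 (chromosome 4), Smarcc1 (chromosome 9), Zzef1 (chromosome 11), Nsd3, Plpp5 and Ddhd2 (chromosome 8), Ubr4 (chromosome 4) and the gamma protocadherin cluster (chromosome 18, 37674392 to 37778142). Over Ubr4, a ubiquitin ligase gene, 14 peaks covered 96.6% of a 104 kb domain, whereas Depdc5 had 91 peaks over 55.3% of its domain.

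**Figure D3:**
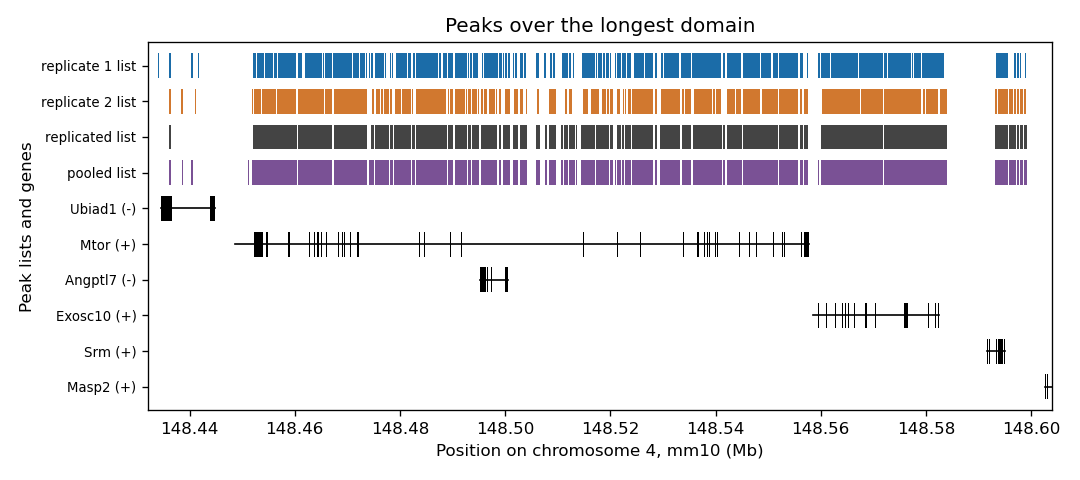
Peaks of the replicate 1, replicate 2, replicated and pooled lists (coloured blocks) and protein-coding genes (lines, with exons as blocks and the strand in brackets) around the longest domain on chromosome 4, by mm10 position (Mb). The domain, 86.2% covered, runs through Mtor and Exosc10 and leaves the start of Mtor free of replicated peaks.

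Called H3K36me3 peaks covered little of the X chromosome. Peaks of the replicated list covered 4.15 kb per Mb of X, the lowest of the 20 chromosomes other than Y (0.0525 kb), against a median of 42.3 kb and a range of 25.9 to 72.9 kb on the autosomes. Of 948 X-linked protein-coding genes 69 were marked, or 7.28% (Wilson 95% interval 5.79% to 9.11%), against 34.0% of autosomal genes, with single autosomes between 24.5% (chromosome 14) and 43.2% (chromosome 8). The X share was 8.86% in replicate 1 and 7.91% in replicate 2, and none of 183 genes on Y was marked.

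**Figure D4:**
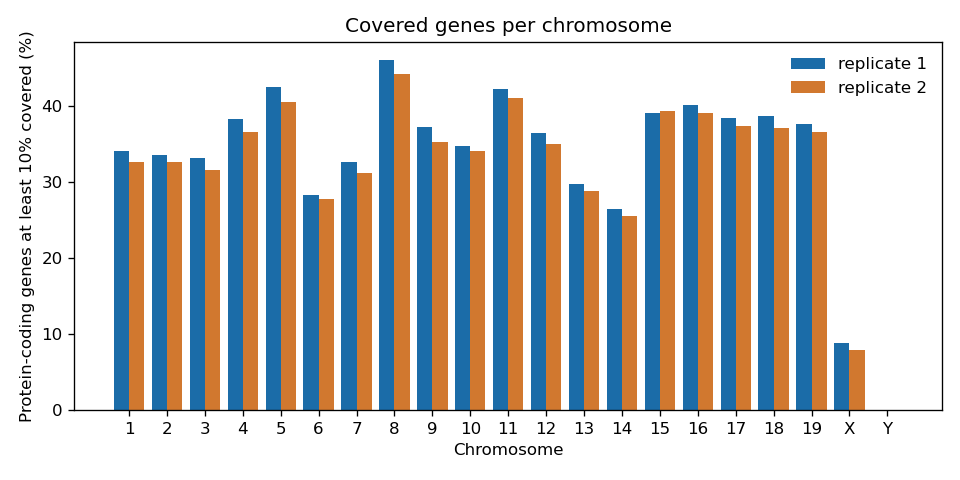
Share of protein-coding genes (%) covered over at least 10% of their length on each chromosome, as bars for replicate 1 and replicate 2. X lies at 8.86% and 7.91%, below every autosome in both replicates, and Y at 0.

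Replicate differences per gene were small beside the range between genes. Among genes of at least 10 kb, those covered most in excess in replicate 1 were the DNA polymerase alpha subunit gene Pola2 (51.9% in replicate 1 and 31.6% in replicate 2), Ccdc127 (34.0% and 15%), Mmp11 (17.3% and 0), the laminin gene Lamb2 (52.8% and 36%) and the DNA repair gene Fance (43.4% and 26.8%). In excess in replicate 2 were the histone chaperone gene Asf1a (11.7% in replicate 1 and 31.1% in replicate 2), the prohibitin gene Phb (42.7% and 62.0%), 1700037C18Rik (41.2% and 60.1%), Chmp7 (49.5% and 66.0%) and Kin (22.4% and 37.2%). With 1 library per replicate these differences were not tested.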

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

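The tests of signal on X, of any peak in X-linked genes, of isolated Zfp genes and of their 3' end were fixed before their results were seen; all other tests in this part were chosen after, among them the values of parts 5 and 10 alone in Zfp genes, and 2 Fisher tests on genes used by few cell classes that replaced tests already run. Outside the comparisons, the replicated list holds 9 peaks on unplaced scaffolds, which no comparison uses; they cover 9801 bp on 6 scaffolds and reach a signal of 9.33. The cause was not tested, and no biological explanation in this part was tested by a design group.

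Few X-linked genes were marked. A lack of widely expressed genes on X is argued against as the whole cause by 6 lists of general machinery and dividing cells (spliceosome, DNA replication, proteasome, RNA polymerase II, ribosomal protein and housekeeping genes). Of their X-linked members 2 of 8 were marked (Nono and Pgk1), against 214 of 242 autosomal members (two-sided Fisher's exact p = 9.59e-05, or 0.000161 with the H3K36 methylation list and 0.00118 without the DNA replication list). These members were not matched on length, and whether X holds fewer such genes was not tested. The 10% minimum is also argued against as the whole cause, since with any peak in both replicates 5 of 8 X-linked and 228 of 242 autosomal members counted (Fisher's exact p = 0.0119, or 0.0125 without the DNA replication list). Lower enrichment of X-linked peaks against the calling threshold stays open: the 99th percentile of the signal on X was 4.56, below the 5.74 to 6.61 of the 19 autosomes. That percentile was taken over the 1148 peaks already called on X. Fewer strongly marked genes on X would lower it too, so it cannot single out this explanation. Whether the lower signal comes from a single active X per cell or from the control could not be separated in these lists.

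None of the 38 spinal interneuron and motor neuron genes, taken here as genes used by few cell classes, was marked. How many cells use each gene was not measured. Gene length is argued against for the spinal interneuron and motor neuron list, with 0 marked genes where 95% of length-matched lists held 7 to 18. A small share of cells using the gene stays open: of the 8 transmitter genes of that list 0 were marked, against 14 of 35 pan-neuronal genes that are not transcription factor genes (Fisher's exact p = 0.0387), but length-matched lists of 8 held 2.91 on average and 0 to 6 in 95% of draws (permutation p = 0.0516). A trait of developmental transcription factor genes also stays open, as 1 of 12 such genes on the neural progenitor list and 8 of its 13 other members were marked (Fisher's exact p = 0.0112), but length-matched lists of 12 held 2.32 on average and as few as 0. These 2 explanations cannot be told apart with so few genes, and the 2 p-values carry little weight because they replaced the length-matched draws of transmitter genes and a test of pan-neuronal against spinal genes (Fisher's exact p = 8.33e-06).

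Zfp genes were marked above chance. Reads shared between neighbouring Zfp genes are argued against as the whole cause. Of 112 Zfp genes with no other Zfp gene within 500 kb 77 were marked, where at most 51 lay in the central 95% of length-matched lists. Related genes under other symbols or farther away were not considered, so reads shared with those stay open. Overlap with other genes is argued against by 208 marked among 312 Zfp genes without overlap, with an upper bound of 128. Coverage concentrated at the 3' end, where the zinc finger array is usually encoded, stays undecided: coverage of part 10 of 10 of the gene body exceeded that of part 5 by 18.8 percentage points in 192 marked Zfp genes of at least 10 kb, against 4.65 to 17.0 in length-matched sets of other marked genes (two-sided permutation p = 0.014). That test used marked genes only, and part 5 was covered less (41.5%) than in the matched sets (47.6% to 57.5%) while part 10 (60.3%) lay within their range (58.6% to 68.0%), which cannot raise the number of marked genes.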

How the results depend on the processing

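The counts of marked members and the pooled-list and single-replicate values for X were added after the data were seen; the other alternatives were fixed before. No result changed direction. The overlap of replicates, the gene body share, the 3' excess and the ratio of X to the autosome median (0.0983) kept their side of the threshold, or stayed within the spread between replicates, under each alternative run. A −log10 q of at least 2 moved the correlation of peak signals to 0.389 and that of covered shares across genes to 0.953. A 25% minimum left 4623 marked genes, a choice of definition, as are the 38899 and 11451 domains at gaps of 1 and 10 kb. Of 202 list medians under alternatives, 200 kept their call; the pan-neuronal median (7.36%) lost it without length matching, and the progenitor median (6.26%) gained it without overlapping genes. Of 173 counts of marked members, 160 kept their call. Pan-neuronal genes lost it at 25% (5 marked), at −log10 q of at least 2 (11), without overlapping genes (10) and with replicate 2 alone (14 marked, against 15 with replicate 1 alone). At 25%, patterning (1), cartilage (1) and histone genes (0) lost it, as did endothelial (1), cartilage (1) and histone genes (0) without overlapping genes, where fewer genes were tested. Protocadherin genes (21) lost it at 5%, and erythroid genes gained it at 5% (2) and with replicate 1 alone (2 with either replicate alone). All 56 protocadherin genes overlap another gene, so they have no value without overlapping genes. Leaving out replicate 2 moved the patterning count from 1 to 3 and kept its call. The cause was not tested for the others. Of 736 values of 184 named genes, 152 moved by more than 1 SD of the replicates. No paired analysis was possible because there is 1 group. The depth of the libraries is unknown, so the effect of depth could not be measured directly. Calling on both replicates together covered 116 Mb, against 86.6 Mb in replicate 1 and 84.1 Mb in replicate 2. Covered bases in the pooled list were 1.52 times the replicate mean on X and 1.31 to 1.41 times on the autosomes. In relative terms X therefore gained the most coverage from pooling.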

Other observations

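The tests in this part were chosen after the data were seen. Within the Hox list the marked genes were Hoxa3, Hoxa5 and Hoxa6, then Hoxb2, Hoxb3, Hoxb4 and Hoxb5, then Hoxd3 and Hoxd4, with none of 9 genes of the C cluster. By position, 9 of 23 genes of paralog groups 1 to 8 were marked and 0 of 16 genes of groups 9 to 13, the genes used toward the tail (two-sided Fisher's exact p = 0.00531). Several of these genes overlap in the annotation, Hoxa3, Hoxa5 and Hoxa6 among them, so peaks cannot be assigned to a single gene there. The Fisher test counted such genes as separate, so its p-value carries little weight. Only 4 marked Hox genes overlap no other protein-coding gene, Hoxb2 to Hoxb5, and these lie side by side. The genes named in this part were chosen after their values were seen.

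Long non-coding RNA genes away from protein-coding genes were rarely marked: of 4100 such genes of at least 2 kb and more than 5 kb from any protein-coding gene, 27 were marked (0.659%). No chance level was computed for this share, and some of the 27 overlap one another. Genes nearer to a protein-coding gene were not counted, such as Tug1, covered over 63.0% and 57.7% in replicates 1 and 2. Snhg17, a small nucleolar RNA host gene, was covered over 69.4% and 70.9% in replicates 1 and 2, and Mir17hg, the host of a microRNA cluster of proliferating cells, over 78.3% and 61.1%. Miat stood at 34.1% and 38.4%, Malat1 at 34.6% and 43.5%, and the imprinted cluster on chromosome 12 showed Mirg at 35.9% and 36.8%. Neat1 had no peak in either replicate.

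Of 21550 domains 526 (2.44%) touched no annotated gene of any type, with a median length of 420 bp, and 290 of them lay within 5 kb downstream of a protein-coding gene, against 34 within 5 kb upstream. The longest, 18.2 kb on chromosome 4 (91211246 to 91229487), lies 21.3 kb downstream of the neuronal RNA-binding protein gene Elavl2 and was covered over 27.8% in replicate 1 and 45.2% in replicate 2. Of the 100 replicated peaks with the highest signal, 37 overlapped a Zfp gene (Wilson 95% interval 28.2% to 46.8%), against 1.99% of all replicated peaks.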
